A study of Homo sapiens with 6 samples.

How the data were processed

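RNA of SiHa cells was measured in 6 libraries, 3 labelled KD and 3 labelled control. Per the labels, total RNA was extracted with a Qiagen RNeasy kit and libraries were made with a SMARTER mRNA-Seq kit. The deposited table of counts holds whole numbers of reads per gene, without normalization by the authors as far as the values show. The deposited table of FPKM values holds, within each sample, the count divided by gene length and library total, times 1 constant per sample, which ranged from 0.944 to 1.14 over the samples. The aligner, the counting program and its use of strand are not given in the sources used here. The submitters' processing notes list the builds hg38, GRCm38 and mm10 with no role. The gene table itself is human: of its 58735 identifiers, 58735 were found in GENCODE 29 at the same coordinates, and its gene lengths equal the union of exons in 100% of genes, so coordinates are given in hg38. Because the use of strand is unknown, reads of overlapping and antisense genes cannot be told apart, and the share of exonic bases shared with another gene is given for MIF, DDT, PYCARD, DUSP6 and IGSF10.

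Samples were placed in groups by their labels. Total counts per library ranged from 14614099 to 16085573, and 3 counts, the floor used for detection, correspond to 0.187 to 0.205 CPM. Counts of every pair of libraries differed by more than sampling noise (chi-square per degree of freedom 3.94 for the closest pair, KD replicates 1 and 3, and 158 for the farthest), so no library was counted as a copy of another. The 10 most abundant genes took 4.64% to 5.46% of the counts.

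KD and control were compared with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr, which left 15802, libraries were scaled with TMM factors (0.889 for KD replicate 2, 0.993 to 1.04 for the others), and the quasi-likelihood F test was run with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, over all genes tested and, where said, over a fixed gene list alone. CPM values use these scaled library sizes, and SE is the standard error of the log2 fold change. On simulated counts for 15802 genes with known changes, the comparison of all 6 libraries recovered 12 of 100 genes changed 2-fold and 93 of 100 changed 4-fold, with 6 unchanged genes called. The comparison without KD replicate 2 recovered 92 of 100 and 100 of 100, with 14 unchanged genes called. The changed genes were drawn only from genes above a set mean CPM, so recovery of genes with low counts was not measured. Genes varied independently and no simulated library stood apart from the others.

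In all, 28 gene lists (pathways, and markers of macrophages, fibroblasts, endothelial cells and lymphocytes) were fixed from general knowledge; 24 had at least 5 tested members and were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 24 lists. Of 906 list entries, 904 were found in the table; H3C2 and H3C3 were not matched. The same test with an estimated correlation, and fry, were alternatives. With an estimated correlation camera also uses the residual degrees of freedom of the libraries, which are few, in place of the number of genes. The samples, the main test, the gene lists, the rule for named genes and the alternatives listed first below were chosen before the data were examined.

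The rule named MIF, TSC22D3, NLRP3, PYCARD, CASP1, IL1B, IL18 and GSDMD, and up to 4 members of each list with the smallest p. It also named the 12 genes with the largest increase and the 12 with the largest decrease among called protein-coding genes with a mean of at least 100 counts whose KD libraries all lay on one side of the control libraries. As no gene was called in all 6 libraries, that last part was applied, after the data were seen, to the comparison without KD replicate 2. Genes of the rule that the text does not name are left out for length.

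Alternatives were DESeq2 size factors, upper-quartile factors, no filter, a filter of 50 counts in 3 samples, DESeq2 1.42.0, limma voom, limma on log2 FPKM with pseudocounts of 1 and 0.1, the replicate number as a block, a loess offset on gene length, and leaving out each library in turn. Offsets on GC content, limma voom with sample weights, 1 surrogate variable from sva 3.50.0, and the alternatives of the comparison without KD replicate 2 were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. A further test on the low MIF counts is not reported here.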

Results

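RNA of SiHa cells, an established line from a human squamous carcinoma of the cervix, was sequenced in 6 libraries, 3 of a KD group and 3 of a control group. The labels spell out neither KD nor its target. The series title concerns macrophage migration inhibitory factor (MIF), a cytokine that acts on macrophages, and the design text also names TSC22D3. Total counts were 14656309, 14734740 and 14803372 in KD replicates 1, 2 and 3, and 14614099, 15303354 and 16085573 in control replicates 1, 2 and 3. At these depths 3 counts correspond to 0.187 to 0.205 CPM (counts scaled to a common library size), a floor that covers counting error only. The labels call the libraries replicate biosamples without saying that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

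The comparison of KD with control asked which transcripts of the tumour cells differed, with the inflammasome and the recruitment of macrophages as the topics of the series. MIF (ENSG00000240972, chromosome 22, 23894004 to 23895227, plus strand, human build hg38) was almost uncounted. It had 2, 1 and 0 counts in KD replicates 1, 2 and 3 and 2, 1 and 1 counts in control replicates 1, 2 and 3, 7 counts in all. The group totals, 3 counts in KD and 4 in control, lay at the floor, so MIF was not tested, no fold change is given, and its level does not check the KD label. Of the 1109 exonic bases annotated for MIF, 61.9% are also exonic in the antisense gene MIF-AS1, which had 29 counts over the 6 libraries. AP000350.4, a gene annotated as protein-coding on the same strand as MIF, shares 32.2% of these bases and had 0 counts. DDT, which encodes the MIF homologue D-dopachrome tautomerase, had 7 counts in all, with 37.8% of its exonic bases shared with another gene. The neighbouring gene SMARCB1, a subunit of a chromatin remodelling complex, had 8498 counts.

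TSC22D3 encodes a glucocorticoid-induced leucine zipper protein (ENSG00000157514, chromosome X, 107713221 to 107777342, minus strand). It stood at 146 ± 7.73 CPM (SD, n = 3) in control and 71.3 ± 14.63 CPM (SD, n = 3) in KD, and was lower in 3 of 3 KD libraries. The log2 fold change was -1.04 (SE 0.18), with an adjusted p of 0.108 over all genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adjusted over the list alone, a list of 10 genes of the MIF pathway of which 5 could be tested, the edgeR p was 0.0020. Without KD replicate 2, which stood apart from the other libraries, TSC22D3 fell by 1.21 on the log2 scale (SE 0.12, edgeR adjusted p = 0.00271 over all genes). That call was lost with a lone KD library, when KD replicate 1 (log2 fold change -1.14, edgeR adjusted p = 0.114) or KD replicate 3 (-1.30, edgeR adjusted p = 0.0838) was left out as well. The study names TSC22D3 and may have chosen it on these samples, so its direction here is not independent evidence. On the same list, adjusted over the list alone, the cell surface receptor subunit CD44 rose by a log2 fold change of 0.73 (SE 0.13, edgeR adjusted p = 0.0020) and TXNIP, which encodes an inhibitor of thioredoxin, rose by 0.77 (SE 0.17, edgeR adjusted p = 0.0040). The list as a whole did not pass (camera adjusted p = 0.184).

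In the KD libraries, 8 of 20 tested factors that recruit or polarise macrophages, 12 of 36 immediate early and ERK feedback genes and 15 of 32 amino acid response genes were lower than in control. Of 43 interferon response genes, 6 were higher, all by edgeR's test adjusted over the list alone. Each list was adjusted on its own, with no adjustment over the lists, and 0 of these genes passed over all genes tested. In these 4 lists, in the order given, 8, 15, 21 and 11 members had an unadjusted edgeR p under 0.05. Of all 15802 tested genes, 2065 did. PTGS2, which encodes cyclooxygenase 2, stood at 33.5 ± 5.78 CPM in control and 7.13 ± 3.40 CPM in KD (SD, n = 3 each). ETV4, a transcription factor induced by ERK signalling, stood at 54.2 ± 5.37 and 18.2 ± 1.56 CPM. PHGDH, the first enzyme of serine synthesis, stood at 903 ± 115 and 400.2 ± 35.3 CPM, and IFIT2, an interferon-induced antiviral gene, at 4.41 ± 0.25 and 10.01 ± 1.14 CPM. In each of these 4 genes every KD library lay on one side of every control library.

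**Figure D1:**
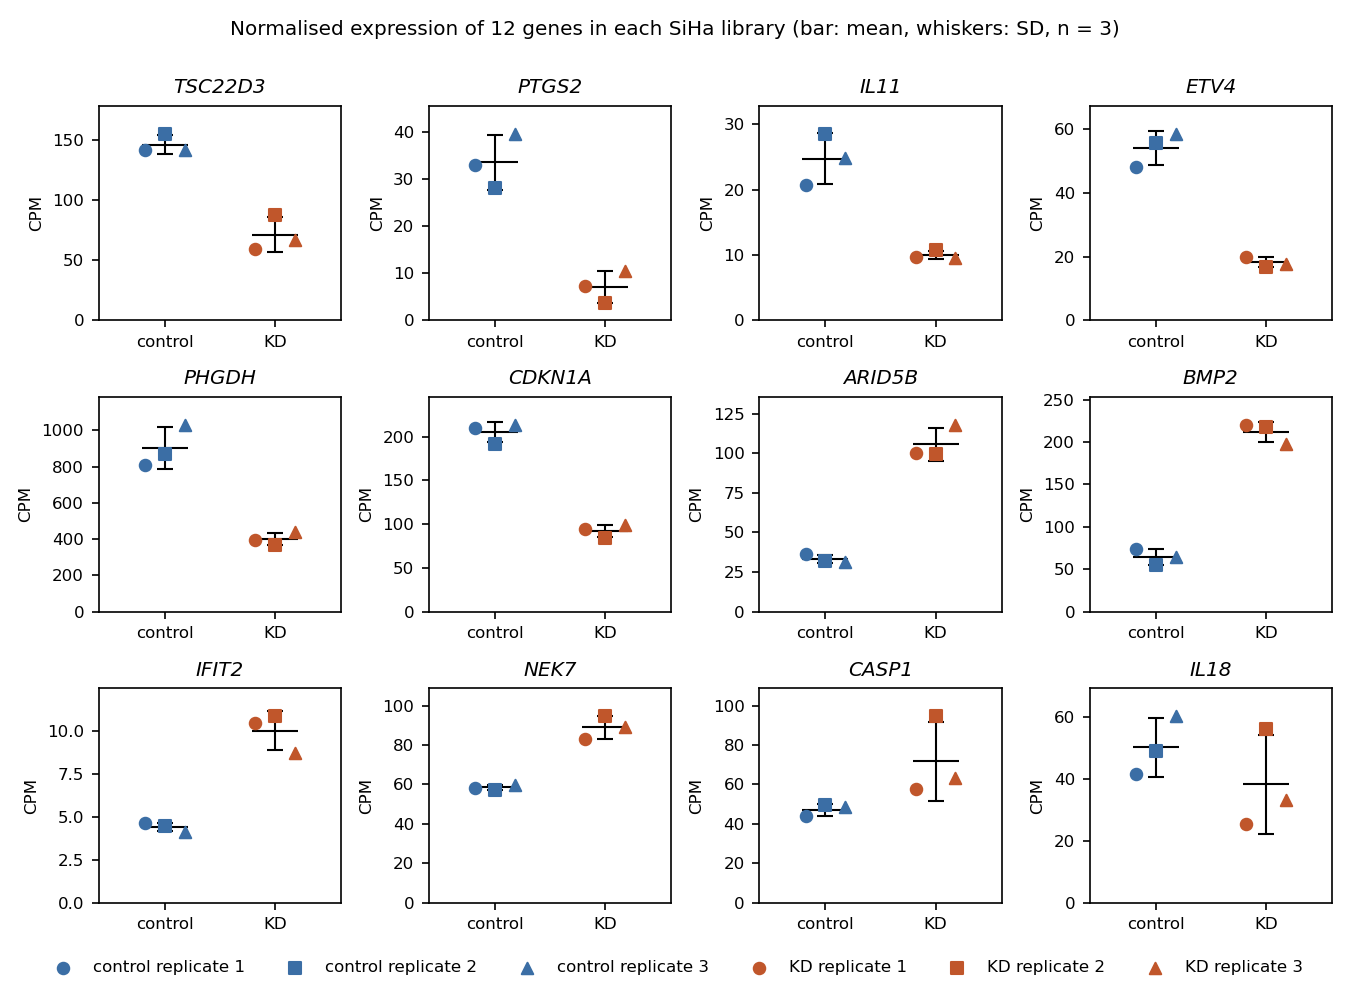
CPM of single genes in each of the 3 control and 3 KD libraries, with points for libraries and a bar and whiskers for the group mean and SD. PTGS2 stood at 33.5 CPM in control and 7.13 CPM in KD on average, and TSC22D3 at 146 and 71.3 CPM.

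Over all 15802 tested genes, edgeR's quasi-likelihood test called 0 in the 6 libraries, with a smallest adjusted p of 0.0623 and 2065 genes at an unadjusted p under 0.05. DESeq2 called 755 genes, 354 higher and 401 lower in KD, and limma voom called 0, with 2079 genes at an unadjusted p under 0.05. In 3543 genes (22.4%) the 3 KD libraries lay entirely above or below the 3 control libraries. The average over the 10 splits into 3 and 3 is 10% for genes without ties, and this share was not set against the other splits. By edgeR, control replicate 1 with KD replicates 1 and 3 against the rest gave 4787 genes at an unadjusted p under 0.05. The excess over 10% is therefore not by itself evidence of a group difference. Without KD replicate 2, edgeR called 1341 genes, 678 higher and 663 lower, of which 345 changed at least 2-fold. That count was 6416 without control replicate 1 as well, 549 without control replicate 2, 142 without control replicate 3, 1 without KD replicate 1 and 5 without KD replicate 3. With a lone KD library left, that library is assumed to vary like the others. Without KD replicate 2 the KD group holds replicates 1 and 3, the closest pair of libraries. Their chi-square per degree of freedom was 3.94, against 8.99 to 30.97 between control libraries. The p-values without KD replicate 2 thus rest in part on the small spread of that pair, which may be technical.

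KD replicate 2 correlated at 0.921 to 0.955 with the other libraries across genes, in log2 CPM, against 0.969 to 0.991 among the other 5. Genes are not independent replicates. The other 5 did not sort by group alone. Control replicate 1 correlated at 0.9826 and 0.9821 with KD replicates 1 and 3, and at 0.9794 and 0.9817 with control replicates 2 and 3. KD replicate 2 had 14887 genes with at least 10 counts, against 15681 to 16061 in the others. Mitochondrially encoded genes gave 2.35% of its counts, against 3.53% to 4.14%. For that reason the gene groups are given for all 6 libraries and without KD replicate 2. Library composition also followed transcript length. Across genes, the Spearman correlation of a library's deviation with gene length was 0.182, -0.248 and -0.245 in control replicates 1, 2 and 3, and 0.322, -0.263 and 0.339 in KD replicates 1, 2 and 3. With GC content the correlation was 0.211, 0.212 and 0.158 in control replicates 1, 2 and 3. It was -0.019, -0.138 and -0.197 in KD replicates 1, 2 and 3. Every KD library thus lay below every control library, so the GC trend went with the group.

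**Figure D2:**
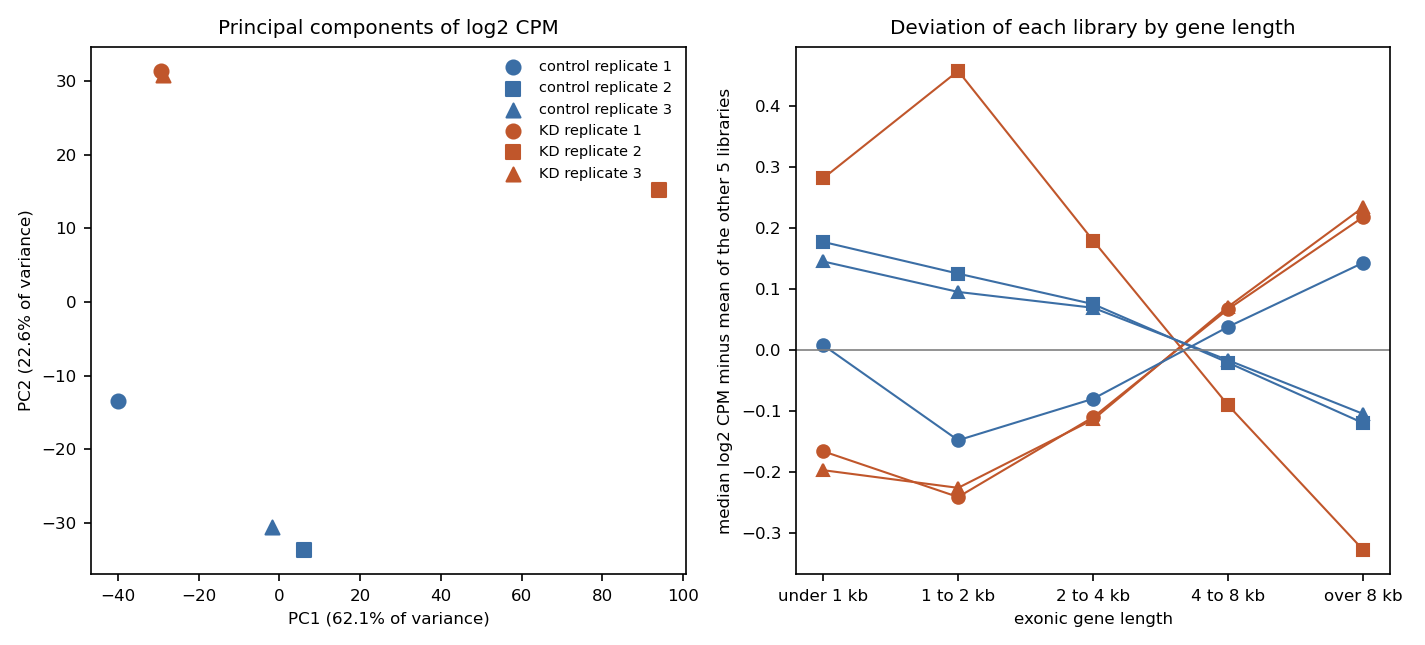
Left, the 6 libraries on the first principal components of log2 CPM, where KD replicate 2 lies apart on the component that holds 62.1% of the variance. Right, the median deviation of each library from the mean of the other 5, in log2 CPM, for bins of exonic gene length; KD replicate 2 and control replicates 2 and 3 lie lower in the longest than in the shortest bin, and the other 3 libraries higher.

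Of 48 listed factors that recruit or polarise macrophages, many were not counted well enough to be tested. Among these were the chemokine genes CCL2, CCL3, CCL4, CCL5, CCL7, CCL8, CCL20 and CXCL10, so nothing is said of them. In all, 20 of the 48 factors were tested. Adjusted over the list alone in all 6 libraries, 8 were lower and 0 were higher in KD by edgeR's test, and 12 did not pass; over all genes tested 0 passed. IL11, a cytokine of the IL6 family, stood at 24.7 ± 3.90 CPM in control and 10 ± 0.61 CPM in KD (SD, n = 3 each), a log2 fold change of -1.30 (SE 0.18, edgeR adjusted p = 0.00321 over the list). LIF, another cytokine of that family, fell by 1.96 (SE 0.37, edgeR adjusted p = 0.00487), and PTGS2 fell by 2.23 (SE 0.37, edgeR adjusted p = 0.00423), on the log2 scale over the list. The neutrophil chemokine CXCL8 had 31, 22 and 74 counts in control replicates 1, 2 and 3 and 1, 1 and 4 counts in KD replicates 1, 2 and 3, so no fold is given. Over all genes tested, 7 of the 20 factors fell and 0 rose by edgeR once KD replicate 2 was left out. The median log2 value over the list, against the control mean, was -0.30, -0.46 and -0.44 in KD replicates 1, 2 and 3, and -0.11, -0.09 and 0.10 in control replicates 1, 2 and 3. The list as a whole stood below other genes by camera (adjusted p = 0.000205 over 24 lists), but not with an estimated correlation between genes (camera adjusted p = 0.31).

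Of 34 inflammasome and pyroptosis genes, 20 were tested, and adjusted over the list alone 1 was higher, 1 was lower and 18 did not pass in all 6 libraries by edgeR. NEK7, a kinase that binds NLRP3, stood at 58.5 ± 1.34 CPM in control and 89.0 ± 5.70 CPM in KD (SD, n = 3 each), a log2 fold change of 0.61 (SE 0.12, edgeR adjusted p = 0.0179 over the list). GSDMB, of the pore-forming gasdermin family, stood at 11.7 ± 0.84 and 5.88 ± 0.99 CPM, a log2 fold change of -0.995 (SE 0.19, edgeR adjusted p = 0.0179 over the list). NLRP3, the sensor of the best known inflammasome, had 1, 3 and 0 counts in control replicates 1, 2 and 3 and 0 in every KD library, and was not tested. CASP1, the protease that inflammasomes activate, stood at 47.3 ± 3.03 CPM in control and 71.8 ± 19.96 CPM in KD (log2 fold change 0.60, SE 0.21, edgeR adjusted p = 0.314 over all genes), which did not pass, and its log2 fold change was 0.35 (SE 0.12) without KD replicate 2, also not past the threshold. IL1B, a cytokine cleaved by CASP1, stood at 1.41 ± 0.31 and 0.58 ± 0.27 CPM and did not pass either (log2 fold change -1.25, SE 0.45, edgeR adjusted p = 0.317). PYCARD, the adaptor of the complex, stood at 1.43 ± 0.61 and 2.66 ± 1.62 CPM, with 59.7% of its exonic bases shared with another gene, and edgeR's adjusted p was 0.579; the log2 fold change was 0.88 (SE 0.54) in all 6 libraries and 0.27 (SE 0.44) without KD replicate 2. GSDMD, the gasdermin that CASP1 cleaves, stood at 212 ± 32.05 and 219.5 ± 98.3 CPM; its log2 fold change was 0.05 (SE 0.31) in all 6 libraries and -0.39 (SE 0.15) without KD replicate 2, neither past edgeR's threshold. IL18, the other cytokine cleaved by CASP1, did not pass in all 6 libraries (edgeR adjusted p = 0.674); without KD replicate 2, where it stood at 56.2 CPM, it fell by 0.78 on the log2 scale (SE 0.18, edgeR adjusted p = 0.0345). Over all genes tested, edgeR called 3 of the 20 genes without KD replicate 2, 1 higher and 2 lower. The list did not stand apart from other genes (camera adjusted p = 0.733 in all 6 libraries).

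Of 37 immediate early and ERK feedback genes, 36 were tested, and adjusted over the list alone 12 were lower, 1 was higher and 23 did not pass in all 6 libraries by edgeR. ETV4 fell by 1.57 on the log2 scale (SE 0.15, edgeR adjusted p = 0.00063 over the list and 0.0623 over all genes). SPRY4, which restrains receptor tyrosine kinase signalling, fell by 1.89 (SE 0.30, edgeR adjusted p = 0.00478 over the list). The phosphatase gene DUSP6, with 40.5% of its exonic bases shared with another gene, fell by 1.51 (SE 0.23, edgeR adjusted p = 0.00478 over the list), and the phosphatase gene DUSP5 fell by 0.89 (SE 0.15, edgeR adjusted p = 0.00561 over the list). With KD replicate 2 left out, 17 of the 36 genes fell and 1 rose over all genes by edgeR, and 12 of these 18 calls stood with corrections for length and for GC content. The list median was -0.49, -0.63 and -0.44 on the log2 scale in KD replicates 1, 2 and 3, against the control mean. By camera the list stood below other genes (adjusted p = 3.94e-08), but not with an estimated correlation (camera adjusted p = 0.31).

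Of 33 genes of the amino acid response driven by the transcription factor ATF4, 32 were tested, and adjusted over the list alone 15 were lower, 1 was higher and 16 did not pass in all 6 libraries by edgeR. PHGDH fell by 1.17 on the log2 scale (SE 0.17, edgeR adjusted p = 0.00762 over the list). The pseudokinase gene TRIB3 fell by 1.41 (SE 0.26), the stress-induced transcription factor gene ATF3 by 1.44 (SE 0.29) and the glutamine transporter gene SLC1A5 by 0.93 (SE 0.19), each with an edgeR adjusted p of 0.0139 over the list. In the 5 libraries without KD replicate 2, 15 fell and 0 rose over all genes by edgeR, and 10 of these calls stood with a correction for GC content. The list median was -0.62, -0.92 and -0.44 in KD replicates 1, 2 and 3. The list stood below other genes by camera (adjusted p = 3.34e-12), but not with an estimated correlation (camera adjusted p = 0.31).

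Of 51 interferon response genes, 43 were tested, and adjusted over the list alone 6 were higher, 0 were lower and 37 did not pass in all 6 libraries by edgeR. IFIT2 rose by 1.18 on the log2 scale (SE 0.19, edgeR adjusted p = 0.0116 over the list), and OASL, of the oligoadenylate synthetase family, rose by 2.20 (SE 0.36, edgeR adjusted p = 0.0116 over the list) from 17, 8 and 14 counts in control replicates 1, 2 and 3 to 71, 50 and 48 counts in KD replicates 1, 2 and 3. CMPK2, a mitochondrial nucleotide kinase gene induced by interferon, rose by 0.58 (SE 0.12, edgeR adjusted p = 0.0201 over the list). Without KD replicate 2, 10 rose and 1 fell over all genes by edgeR. With a correction for GC content 8 of these 11 calls stood, and that of the interferon-induced helicase gene DDX60 was among the lost (log2 fold change 0.83 before and 0.73 after, edgeR adjusted p = 0.0385 and 0.0604). The list median was 0.32, 0.11 and 0.32 in KD replicates 1, 2 and 3. The list stood above other genes by camera (adjusted p = 0.0003), but not with an estimated correlation (camera adjusted p = 0.168). That estimate was -0.021, below the preset 0.01, so a larger correlation between genes was not the reason for the loss.

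Of 22 glucocorticoid responsive genes, 20 were tested, and adjusted over the list alone 6 were lower, 2 were higher and 12 did not pass in all 6 libraries by edgeR. GADD45B, a stress-induced growth arrest gene, fell by 1.31 on the log2 scale (SE 0.26, edgeR adjusted p = 0.0102 over the list), and DUSP1, which encodes a MAP kinase phosphatase, fell by 0.86 (SE 0.18, edgeR adjusted p = 0.0112 over the list). CRISPLD2, a secreted protein gene, rose by 1.39 (SE 0.27, edgeR adjusted p = 0.0102 over the list). Without KD replicate 2, 5 fell and 2 rose over all genes by edgeR, and the list median was -0.41, -0.54 and -0.34 in KD replicates 1, 2 and 3. TSC22D3 is also on this list, and the lists share other members, ATF3, LIF and VEGFA among them. Camera placed the list below other genes (adjusted p = 0.0279), which was lost with an estimated correlation (camera adjusted p = 0.31), without control replicate 1 (camera adjusted p = 0.0688), without control replicate 3 (0.0784) and without KD replicate 1 (0.0546).

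Of 50 genes of the G1/S transition and DNA replication, 49 were tested, and adjusted over the list alone edgeR called 0 in all 6 libraries, with 8 at an unadjusted p under 0.05. Camera placed the list below other genes (adjusted p = 0.00287, median log2 fold change -0.12), but not with an estimated correlation (camera adjusted p = 0.168). Here too the estimate, -0.019, lay below the preset 0.01, so a larger correlation was not the reason for the loss. Without KD replicate 2, 5 fell and 0 rose over all genes by edgeR, among them E2F1, a transcription factor of S-phase entry (log2 fold change -0.67, SE 0.12, edgeR adjusted p = 0.0152), and RRM2, a subunit of ribonucleotide reductase (-0.67, SE 0.14, edgeR adjusted p = 0.0246).

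Nuclear genes of oxidative phosphorylation followed KD replicate 2. Their list median was 1.25 on the log2 scale in KD replicate 2, -0.19 in KD replicate 1 and -0.25 in KD replicate 3. Camera placed the 43 genes above others in all 6 libraries (adjusted p = 0.00738), not with an estimated correlation (camera adjusted p = 0.777) nor without control replicate 1 (camera adjusted p = 0.243), and the direction turned without KD replicate 2 (camera adjusted p = 0.173). The 71 ribosomal protein genes had a median of 1.04 in KD replicate 2 and -0.36 in both KD replicate 1 and KD replicate 3. Camera gave an adjusted p of 0.332 above other genes in all 6 libraries, 0.0177 above them without control replicate 2, 0.00117 without KD replicate 1 and 0.000898 without KD replicate 3, and 1.25e-07 below them without KD replicate 2, the latter lost with an estimated correlation (camera adjusted p = 0.748). The 13 mitochondrially encoded genes had a median of -0.95 in KD replicate 2, -0.18 in KD replicate 1 and 0.07 in KD replicate 3, and did not pass in all 6 libraries (camera adjusted p = 0.164), but stood below other genes without KD replicate 3 (camera adjusted p = 0.0158).

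**Figure D3:**
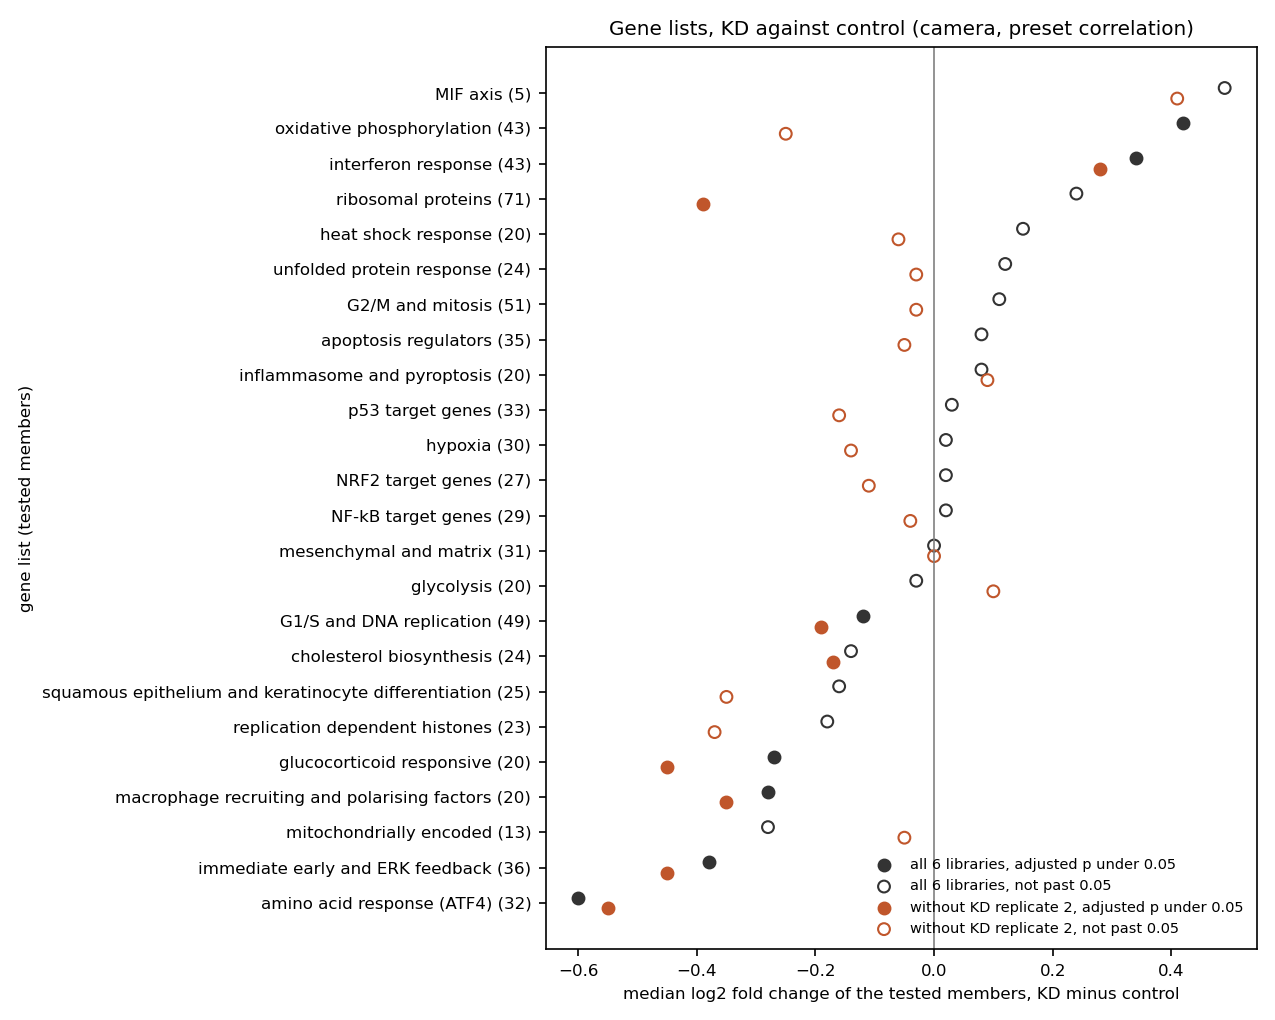
Median log2 fold change, KD against control, of the tested members of each gene list, in all 6 libraries (black) and without KD replicate 2 (orange), filled where the camera adjusted p at the preset correlation was under 0.05. The amino acid response list stood at -0.60 and -0.55, and the oxidative phosphorylation list at 0.42 and -0.25.

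The genes with the largest fold changes were taken from the comparison without KD replicate 2, since none passed in all 6 libraries. The protease inhibitor gene A2M rose most (log2 fold change 2.51, SE 0.22, edgeR adjusted p = 0.00147), from 4.46 ± 1.24 CPM in control to 22.04 ± 5.92 CPM in all 3 KD libraries (SD, n = 3 each); it shares sequence with its paralogue PZP, which rose by 1.65 (SE 0.23). ARID5B, a chromatin regulator, stood at 33.2 ± 2.7 and 105.9 ± 10.4 CPM and rose by 1.71 (SE 0.13, edgeR adjusted p = 0.000951). BMP2, a secreted ligand of the TGF-beta family, stood at 63.9 ± 9.39 and 211.9 ± 11.98 CPM and rose by 1.71 (SE 0.14, edgeR adjusted p = 0.000951). The kinase gene MAP2K6, which acts on p38, rose by 1.92 (SE 0.21), the guanine nucleotide exchange factor gene VAV3 by 1.86 (SE 0.20), the monoamine oxidase gene MAOB by 1.54 (SE 0.14) and the nuclear receptor gene NR4A3 by 1.53 (SE 0.15). MARCOL and IGSF10 rose by 2.34 (SE 0.40) and 2.29 (SE 0.18) without KD replicate 2, but stood at 2.14 and 4.97 CPM in that library, against control means of 3.98 and 4.91 CPM; 31% of the exonic bases of IGSF10 are shared with another gene. ADARB2 rose by 1.58 (SE 0.28), with 5.81 CPM in KD replicate 2 below the 6.15 CPM of control replicate 1, and CRISPLD2 by 1.5 (SE 0.24), which completes the 12 genes of largest increase.

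Among the 12 genes of largest decrease, the chemokine gene CXCL2 fell by 2.96 (SE 0.54, edgeR adjusted p = 0.0154), from 20.35 ± 14.01 CPM in control to 3.45 ± 1.48 CPM in all 3 KD libraries (SD, n = 3 each); it shares sequence with other chemokine genes. The apolipoprotein gene APOE fell by 2.00 (SE 0.34), PTGS2 by 1.92 (SE 0.21) and LIF by 1.66 (SE 0.22). NXPH4, which encodes a neurexophilin, stood at 81.4 ± 5.98 CPM in control and 24.5 ± 3.91 CPM in KD and fell by 1.61 (SE 0.13, edgeR adjusted p = 0.000951). UBE2QL1 fell by 1.80 (SE 0.21), PMEPA1, an inhibitor of TGF-beta signalling, by 1.78 (SE 0.30), WFIKKN1 by 1.77 (SE 0.21), CASKIN1 by 1.76 (SE 0.18), the taste receptor gene TAS1R3 by 1.66 (SE 0.17), the tight junction gene CLDN9 by 1.66 (SE 0.22) and the dexamethasone-induced gene RASD1 by 1.61 (SE 0.23). In APOE the libraries of the groups overlapped once KD replicate 2, at 13.8 CPM, was counted. Each of the 24 genes of largest change was also called by edgeR after a correction for gene length and after one for GC content.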

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

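The GC offset, the sample weights, the surrogate variable and every alternative of the comparison without KD replicate 2 were chosen only after the result was seen. edgeR with other size factors, a stricter filter, the GC offset or a left-out library other than KD replicate 2, and limma on FPKM values, also called 0 genes, with 1104 to 2651 genes at an unadjusted p under 0.05. Where the count moved, no filter gave 59 genes (21 higher, 38 lower, 59 at least 2-fold), the length offset 5 (4, 1 and 5), DESeq2 755 (354, 401 and 259), voom with sample weights 4210 (2186, 2024 and 759) and 1 surrogate variable 4868 (2410, 2458 and 576). Leaving out 1 library gave from 0 to 1341 genes called, 0 to 678 higher, 0 to 663 lower and 0 to 345 at least 2-fold, the highest without KD replicate 2, where the edgeR dispersion was 0.0190 against 0.0752 in all 6 libraries. The voom sample weight was 0.107 for KD replicate 2 and 0.618 to 2.273 for the other libraries. The surrogate variable stood at -0.829 in KD replicate 2 and at -0.113 to 0.319 in the other libraries. Both alternatives thus mainly reduced the part of KD replicate 2, as leaving it out does, and are not separate evidence. The cause of the moves with no filter, the length offset and DESeq2 was not tested.

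Inflammasome genes called over all genes numbered 2 with DESeq2, 8 with sample weights, 8 with 1 surrogate variable and 0 to 3 with a library left out. Macrophage factors called numbered 5 with no filter, 6 with DESeq2, 9 with sample weights, 10 with 1 surrogate variable and 0 to 7 with a library left out. TSC22D3 kept its direction in every alternative run, with log2 fold changes from -1.30 (without KD replicates 2 and 3) to -0.92 (without KD replicate 1). It passed the threshold with DESeq2 (-1.03), sample weights (-1.20), 1 surrogate variable (-1.11) and without KD replicate 2 (-1.21), and over its alternatives the adjusted p ran from 9.57e-14 (DESeq2 without KD replicate 2) to 0.527. MIF, at the floor in both groups, was given no fold change under any alternative.

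GSDMD turned negative with voom (-0.022), limma on log2(FPKM + 1) (-0.02), on log2(FPKM + 0.1) (-0.022) and on unfiltered FPKM (-0.02), the replicate block (-0.028), the block with the length offset (-0.001), sample weights (-0.41, limma adjusted p = 0.0379), 1 surrogate variable (-0.15), without control replicate 1 (-0.07) and without KD replicate 2 (-0.39), against at most 0.23 with another library left out. It also passed as lower without KD replicate 2 and control replicate 1 (-0.50, edgeR adjusted p = 0.000213); the cause was not tested. In the comparison without KD replicate 2 and with 1 more library left out, PYCARD ran from -0.043 without KD replicate 2 and control replicate 1 to 0.49 without KD replicate 2 and control replicate 2; the cause was not tested. In the comparison without KD replicate 2, the GC offset called 837 genes, DESeq2 2029, and leaving out 1 more library from 1 (KD replicate 1) to 6416 (control replicate 1), with 549, 142 and 5 for control replicate 2, control replicate 3 and KD replicate 3. The cause of these moves was not tested, except that the smallest counts rest on a lone KD library.

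Among the gene lists, 0 passed with an estimated correlation, in all 6 libraries and without KD replicate 2, against 7 and 8 at the preset correlation. In all 6 libraries the estimate was -0.021 for the interferon list and -0.019 for the G1/S list, below the preset 0.01. It was 0.026 to 0.75 for the other lists that had passed. A larger correlation can therefore not be the reason for the loss of the interferon and G1/S lists. With this setting camera also uses the few residual degrees of freedom of the libraries. The loss of a list therefore does not by itself show that its members move together. With fry's direction test 5 and 7 passed; in all 6 libraries it lost the amino acid list (adjusted p = 0.0524), the glucocorticoid list (0.0524) and oxidative phosphorylation (0.825), and gained p53 targets (0.0181). Directions turned for G2/M without control replicate 1 (camera adjusted p = 0.975), glycolysis without control replicate 3 (0.997) and KD replicate 1 (0.869), and ribosomal proteins without control replicate 1 (0.687). Without KD replicate 2 they turned for the unfolded protein response (0.999), apoptosis (0.863), oxidative phosphorylation (0.173), ribosomal proteins (1.25e-07) and heat shock (0.429); the cause was not tested. Over the left-out libraries camera's adjusted p ran from 0.0112 to 0.975 for G2/M, 0.66 to 0.997 for glycolysis, 0.293 to 0.999 for the unfolded protein response, 0.726 to 0.955 for apoptosis, 6.57e-06 to 0.243 for oxidative phosphorylation, 1.25e-07 to 0.687 for ribosomal proteins and 0.178 to 0.975 for heat shock. Same-numbered libraries deviated together with correlations of 0.63, 0.513 and -0.267 for replicates 1, 2 and 3. Controls of another number reached -0.321 with KD replicate 1, 0.329 with KD replicate 2 and 0.602 with KD replicate 3. These values do not settle whether the numbers pair the samples. With the replicate block edgeR called 0 genes, 2138 at an unadjusted p under 0.05, and the dispersion was 0.0472. For the single genes named beside these results, 1394 values kept direction and side of the threshold, 257 passed it newly, 136 no longer passed it and 11 reversed. Low counts limit what can be said of MIF, NLRP3, DDT and CXCL8, each with under 5 counts in every KD library.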

Other observations

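The tests of a removed MIF transcript, of a loss of long transcripts, of a length trend behind the gene lists and of other splits of the libraries were chosen only after the result was seen, as were the corrections applied without KD replicate 2.

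Of 33 tested p53 target genes, 5 were lower and 0 higher in KD in all 6 libraries, adjusted over the list alone by edgeR, and 28 did not pass. CDKN1A, the cell cycle inhibitor p21, stood at 205 ± 11.5 CPM in control and 92.5 ± 7.15 CPM in KD (SD, n = 3 each), a log2 fold change of -1.15 (SE 0.13, edgeR adjusted p = 0.00215 over the list). GADD45A, a growth arrest gene, fell by 1.24 on the log2 scale (SE 0.30, edgeR adjusted p = 0.0387 over the list). The list's median was 0.03 and its mean -0.19, and it did not stand apart from other genes (camera adjusted p = 0.184), while fry, which tests whether the members move one way on balance, gave an adjusted p of 0.0181. Of 31 tested mesenchymal and matrix genes, 4 were lower, 1 was higher and 26 did not pass, adjusted over the list alone by edgeR. CYR61, a matricellular protein gene induced by YAP, stood at 2322 ± 124 CPM in control and 969 ± 88.5 CPM in KD and fell by 1.26 (SE 0.17, edgeR adjusted p = 0.00454 over the list), and the related gene CTGF fell by 1.17 (SE 0.23, edgeR adjusted p = 0.0149 over the list). Camera gave that list an adjusted p of 0.184.

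Of 30 tested hypoxia genes, 4 were lower and 0 higher adjusted over the list alone by edgeR. The angiogenic factor gene VEGFA fell by 1.19 (SE 0.23, edgeR adjusted p = 0.0365 over the list) and the peptide hormone gene ADM by 1.04 (SE 0.26, edgeR adjusted p = 0.0499 over the list), while the list's median was 0.02 and its mean -0.21 (camera adjusted p = 0.222). Of 25 tested squamous differentiation genes 2 were lower and 0 higher, and the tight junction gene CLDN1 fell by 1.53 (SE 0.27, edgeR adjusted p = 0.0159 over the list; camera adjusted p = 0.242). Of 35 apoptosis regulators 1 was higher and 1 lower, and the caspase gene CASP9 rose by 0.88 (SE 0.15, edgeR adjusted p = 0.0245 over the list; camera adjusted p = 0.822). Adjusted over the list alone edgeR called 0 in all 6 libraries for 29 NF-kB target genes, 51 G2/M genes, 20 glycolysis genes, 24 unfolded protein response genes, 24 cholesterol synthesis genes, 27 NRF2 target genes, 23 histone genes and 20 heat shock genes, with 5, 6, 4, 4, 0, 6, 2 and 1 at an unadjusted p under 0.05. Camera's adjusted p for these 8 lists ran from 0.164 for histones to 0.778 for glycolysis; histones passed below other genes without control replicate 2 (0.0423) and G2/M genes above them without control replicate 2 (0.0112). Median and test differed in sign for glycolysis (median -0.03, above other genes), NF-kB targets (median 0.02, mean -0.01, below) and NRF2 targets (median 0.02, below). Cholesterol synthesis passed below other genes without KD replicate 2 (camera adjusted p = 0.0369), not with an estimated correlation (camera adjusted p = 0.68). Of markers of other cell types, macrophage markers summed to 39.8 to 73.1 CPM per library (97.5% of it CD14), fibroblast markers to 56.2 to 145 CPM (99.5% COL1A1), endothelial markers to 11.6 to 19.96 CPM and lymphocyte markers to 1.38 to 2.90 CPM. Of these markers 1 macrophage, 1 fibroblast, 3 endothelial and 2 lymphocyte genes were tested, and only the adhesion gene ESAM passed, which fell by 1.19 on the log2 scale (SE 0.17, edgeR adjusted p = 0.00078, adjusted over the list alone).

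MIF was nearly absent from all 6 libraries, a gene that tumour lines usually express. Whether KD removed the transcript cannot be told, since the control libraries held a mean of 1.33 counts and the gene's reads may have gone uncounted. Reads over exons of 2 overlapping genes may have been left uncounted: 38.1% of MIF's exonic bases and 44.9% of its principal transcript lie in no other gene, more than this explanation allows by the bound set in advance, but they form 1 stretch at the 5' end of which RefSeq's transcript holds 43 bases, and 345 of 345 coding bases are shared, so this stays open. Of protein-coding genes with 50% to 95% of exonic bases shared, 59.9% had a mean under 10 counts, against 38.1% with under 5% shared, 22.4% with 5% to 50% and 98.9% with 95% or more.

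KD replicate 2 stood apart from the other libraries. A control library under a KD label is argued against by the 500 genes most different between KD replicates 1 and 3 and control replicate 1. Of these, 91.6% differed the same way between KD replicate 2 and control replicates 2 and 3. Of the genes called without it, 72.1% lay on the called side in it, against 64.7% to 68.6% in 20 simulations, a narrow margin. Their median log2 difference from control in KD replicate 2 was 0.26 for the higher and -0.53 for the lower genes. In KD replicates 1 and 3 it was 0.68 and -0.8. For RNA of other cell types, the highest ratio of a marker sum in KD replicate 2 to that of any other library was 1.32, for macrophages. CD14 made up 97.5% of the macrophage sum and COL1A1 99.5% of the fibroblast sum. A rise of their other markers would hardly move these sums, so they decide nothing for those cells. The endothelial and lymphocyte sums stood at 0.579 and 0.475 of the highest other library, so neither rose in KD replicate 2. ESAM made up 51.3% of the endothelial sum and was lower in every KD library than in every control library. The lymphocyte sum in KD replicate 2 was only 1.38 CPM. These sums therefore cannot exclude a small amount of RNA of endothelial cells or lymphocytes. Trends with gene length and GC content were not the whole deviation, since the SD over genes was 0.722 after they were removed, against at most 0.371 elsewhere. Gene length here is the union of exons, not the length of the transcript expressed, so a loss of long transcripts stays open. The cause stays open, a difference of the cells in that sample included, which was not tested.

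The 1341 genes called without KD replicate 2 may in part follow trends of length or GC content that differ between the groups. With a length correction 79.6% kept call and direction, and with a GC correction 56.3%, between the bounds of 50% and 80% set in advance, so neither can be told apart from the group difference for the genes that were lost. In those the median absolute log2 fold change went from 0.58 to 0.40 with the length correction (SE 0.144 to 0.127) and from 0.62 to 0.52 with the GC correction (SE 0.15 to 0.147), so the median fold was smaller at a similar or smaller SE; fewer calls also make the adjusted threshold stricter with the GC correction, and these were not told apart. All 1341 genes kept their sign in both.

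A hypothesis was that the lists past camera's threshold in all 6 libraries may rest on a length trend that libraries of both groups share. KD replicates 1 and 3 were set against control replicate 1, and KD replicate 2 against control replicates 2 and 3, sets of like length trend. In both, 7 of the 7 lists had a median on the list's side, against 8 of the 17 lists that had not passed. The 7 were chosen by their direction in these same libraries, which favours that outcome, so the test decides nothing. Without KD replicate 2, edgeR called 15 amino acid, 18 immediate early, 7 macrophage factor, 11 interferon, 7 glucocorticoid, 5 G1/S and 2 oxidative phosphorylation genes. With the length correction it called 14, 15, 7, 13, 7, 7 and 3. These counts argue against a length trend as the whole cause of those calls. With the GC correction edgeR called 10, 13, 6, 8, 7, 4 and 0, fewer in every list but the glucocorticoid one. A GC trend therefore stays open for the calls that were lost. For camera in all 6 libraries both trends stay open, as camera was run with neither correction. The 10 splits of the 6 libraries are too few for a share under 0.05: the real one gave 2065 genes at an unadjusted p under 0.05, and 2 of 10 gave as many, the other being control replicate 1 with KD replicates 1 and 3 against the rest, with 4787, which points to a structure of the samples.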
